A study of Daphnia magna with 24 samples.

How the data were processed

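The intensity values are single-channel scanner intensities as deposited: whole numbers with a ceiling of 65535, no background subtraction seen, and arrays not scaled to each other. Per the labels, RNA from whole animals (about 20 per exposure) was extracted with Trizol, and 300 ng was labelled with Cy3 using the Agilent Quick-Amp kit; scanner and extraction settings are not given in the sources used here. The log2 values in the authors' deposited table are ratios of each exposure over the media control, rounded to 1 decimal and present only for some features; per the labels they rest on 16 array-by-array comparisons per exposure, and their normalization, test and threshold are not given in the sources used here. The E values in the same table are, per the file headers, expectation values of sequence searches against an NCBI protein database and Daphnia pulex assemblies. E values were used only to choose which names count.

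All 24 arrays in 6 groups of 4 were used. On Ag+ 2, 310 features were exactly 0 and were treated as missing. For set tests they were filled with the group mean. Among them are hemoglobin DM01561P3, DM01720P1 and vitellogenin DM01857P2, whose Ag+ values rest on the other Ag+ arrays. Intensities were corrected with normexp at an offset of 50, put on the log2 scale and quantile-normalised. The offset pulls log2 differences of dim features toward 0, so their folds are understated; a feature is called dim below 2 times the lower quartile of its array, and where that holds for all arrays of 1 side, or for some and raising them to the limit moves the value by over 0.5, a lower bound of the fold is given for features that pass. Bounds are on the normalised scale and are left out where they are not above 1-fold, where both sides are dim, or where they exceed the ratio of mean intensities; such features are only called dim. The scaling rule fixed before the data were examined assumed values already near a log2 scale (shift to a common 75th percentile); because the files hold raw intensities, normexp with quantile normalization was used instead and the literal rule was run as an alternative.

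Differences were tested with limma: 1 mean per group over all 24 arrays, contrasts, eBayes without trend (prior df 1.59), two-sided moderated tests, and Benjamini-Hochberg adjustment over 14338 features at 0.05. All adjusted p-values of features in the text are from this limma fit, with SE of the contrast. The mean of the 16 pairwise ratios of an exposure equals the difference of group means, so the test rests on 4 against 4 arrays and not on 16 replicates. Contrasts were each exposure against Control, each nanowire against Ag+, coating, length, their interaction, and the simple effects. With 4 arrays per group, an exact test on 4 against 4 cannot go below p = 0.0286. Each exposure was given at its own dose, so silver mass may differ between groups; this was not tested.

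Samples, contrasts, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names, for each exposure against Control, up to 10 risers and 10 fallers that pass, carry a gene name, and have no overlap between exposed and Control arrays; up to 5 and 5 for the other contrasts; the 3 with the smallest p where none pass; 4 members of each list past its test; and all vitellogenin and hemoglobin features. Unnamed features in the text were chosen after values were seen. Names come only from the authors' table, which covers 1826 of 14338 features: 1024 have a description, 434 of these a significant match (E of 0.001 or less) and 271 a gene name. The reference pairing of locus tags with symbols was not used for names, and no coordinates were used.

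Gene lists were made by word match. Of 26 lists, 10 had at least 5 members and were tested in 5 exposures (50 tests) with camera at a preset correlation of 0.01 against the 434 features with a significant match; fry and an estimated correlation were run beside it. The metallothionein, ABC transporter, copper and zinc, histone and cell cycle, carbohydrate and algal food lists had 0 members. Exact permutation of list scores gave a smallest p of 0.0286, adjusted p = 0.0894. List membership rests on features the authors selected on these samples, so list results are not independent evidence.

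Alternatives fixed in advance were quantile normalization without background correction, median centring, leaving out the 0.25 of features with the lowest mean, fitting only the arrays compared, array weights, eBayes with trend and robust, features with a value on all arrays, the replicate number as a block over the 20 numbered arrays, and leaving out each array. Alternatives added after the data were seen were 2 scalings to a common 75th percentile (raw, and after normexp over bright features), the first residual principal component as a covariate, the array floor as a covariate, features with a mean intensity over 200, and for lists a background of all features and members with any match. Labels were also exchanged between groups: all 35 splits of 8 arrays, and 100 random splits for contrasts over more arrays. Overlaps between exposures were set beside 100 simulations of unchanged groups that share a Control, and Control arrays were split 2 and 2.

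A self-test added known changes to simulated arrays and passed them through the same fit. The first version drew noise from unscaled log2 values and missed its gate: it found 8 of 10 bright 4-fold changes (80%), where more than 80% was required, with 62% of all 2-fold and 94% of all 4-fold changes, and 22.7% of bright 2-fold changes; 5.5% of calls were false. The simulation was then revised to draw noise from quantile-normalised values. The revised version found 76.2% of 2-fold (381 of 500) and 93.6% of 4-fold changes (468 of 500), 50.5% of bright 2-fold (50 of 99) and 90.9% of bright 4-fold changes (80 of 88), with 4.7% false calls and 1 call in 12 contrasts with no change. In both versions noise was drawn independently for each feature, without the variation that features share on the real arrays. These error rates therefore need not hold for the real arrays. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.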

Results

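The series measured transcript levels in whole Daphnia magna, a freshwater crustacean used as a test animal in aquatic toxicology. Animals were kept for 24 h in medium alone (Control), with dissolved silver (Ag+), or with 1 of 4 silver nanowire preparations, each at 1/10 of its own LC50. The nanowires were long (L) or short (S) and coated with polyvinylpyrrolidone (PVP) or silica (SiO2), giving L-PVP-NW, L-SiO2-NW, S-PVP-NW and S-SiO2-NW. Each of the 6 groups has 4 single-colour arrays, 24 in all, with 14338 features per array. Vitellogenin, ribosomal protein, myosin, cuticle protein and digestive protease transcripts are the named groups with the largest differences described below. At least 1 of the 5 exposures differed from Control for 3203 features (22.3%; limma F test, adjusted p under 0.05 over all features).

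Most features gave little signal. Median intensities ran from 60 to 72 over the 24 arrays, and 3513 to 5292 features per array (24.5 to 36.9%) stood above 2 times the array's lower quartile. Replicates within a group correlated at r = 0.918 to 0.977. The 1st percentile of intensity, here called the array floor, was 47.5 ± 1.91 in Control (SD, n = 4), 45.75 ± 0.5 in Ag+, 48.75 ± 0.957 in L-PVP-NW, 41.75 ± 0.957 in L-SiO2-NW, 42.25 ± 0.957 in S-PVP-NW and 43.59 ± 1.44 in S-SiO2-NW. Every array of both SiO2 groups and S-PVP-NW has a lower floor than every Control array, so an effect of slide or scan cannot be told apart from an effect of these 3 exposures. Floors in Ag+ (45 to 46) met those in Control (46 to 50) only at 46. Features at the intensity ceiling numbered 0 on every Ag+ array and 5 to 9 on the Control arrays. A slide or scan difference is therefore not excluded for Ag+ against Control either. The floors of L-PVP-NW, L-SiO2-NW and S-PVP-NW are separated from those of Ag+ as well, and those of L-PVP-NW from both L-SiO2-NW and S-PVP-NW, with the same limit for these contrasts. The p-values measure spread between these arrays, and whether replicates came from separate cultures is not given in the sources used here. The first principal component of differences from the group means held 26.3% of that variance and placed 2 arrays of every group below 0 and 2 above, 12 and 12 in all. In each of the 5 numbered groups replicates 1 and 3 lay on 1 side and 2 and 4 on the other, with 1 and 3 below 0 in Control, Ag+ and S-SiO2-NW and above 0 in L-SiO2-NW and S-PVP-NW. In L-PVP-NW replicates A and D lay below 0. What sets these arrays apart was not tested.

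**Figure D1:**
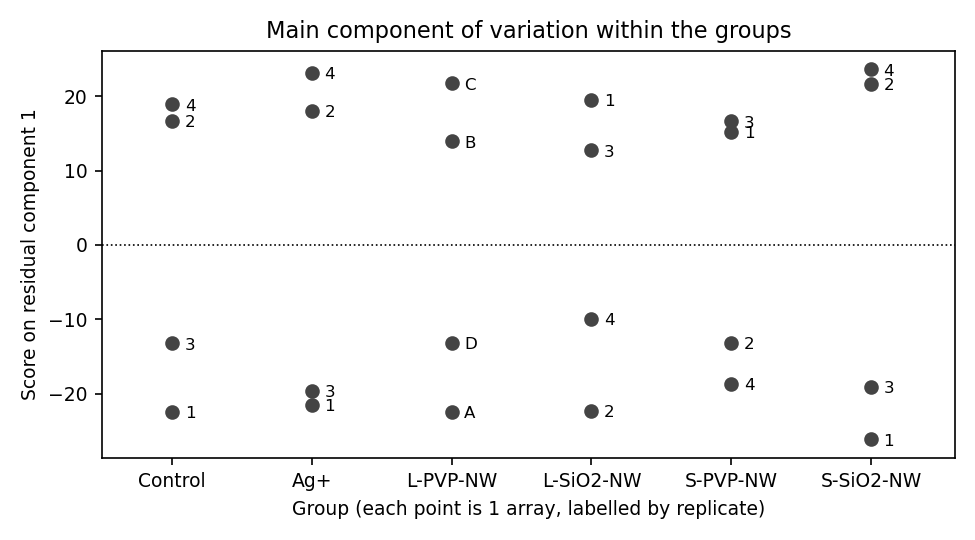
Score of each array on the first principal component of differences from the group means. Each point is 1 array (n = 4 per group).

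Dissolved silver lowered transcripts for yolk, ribosomal and muscle proteins. The feature with the largest named fall, vitellogenin fused with superoxide dismutase (DM02775P1), encodes a yolk precursor and fell by 8.51 ± 0.89 log2 units in Ag+ (SE, n = 4 arrays per group; adjusted p = 1.32e-05), with intensities of 88 ± 64 in Ag+ and 36670 ± 15200 in Control (SD). On 3 of the 4 Ag+ arrays it was dim, so its fall is given as at least 245-fold (−7.94). Muscle myosin heavy chain (DM00704P3), the motor of the thick filament, fell by 2.72 ± 0.27 (adjusted p = 8.21e-06; 72.5 ± 7.51 against 405.8 ± 36.2), and ribosomal protein L44 (DM02282P1) fell by 2.95 ± 0.34 (adjusted p = 3.98e-05; 262.2 ± 120 against 1416 ± 257). Myosin was dim in Ag+, so its fall was at least 4.74-fold. In the other direction, 2 subunits of the respiratory chain encoded in mitochondrial DNA rose: cytochrome c oxidase subunit I (DM01562P1) by 2.08 ± 0.40 (adjusted p = 0.00152; 16990 ± 5910 against 4292 ± 1590) and NADH dehydrogenase subunit 5 (DM02802P1) by 1.63 ± 0.26 (adjusted p = 0.000433; 16300 ± 3960 against 5575 ± 2220). Another subunit of the chain, ubiquinol-cytochrome c reductase 14 kD (DM02249P3), fell by 1.66 ± 0.42 (adjusted p = 0.00968; 204.8 ± 70.3 against 499.5 ± 147).

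Among the 10 vitellogenin and oogenesis features, 6 fell in Ag+ and none rose over all features (7 fell when adjusted over the list alone), with a list median of −1.85. Besides DM02775P1, vitellogenin features DM01546P3 (−2.72 ± 0.60, adjusted p = 0.00409), DM02255P1 (−2.47 ± 0.68, 0.0153), DM00120P2 (−2.38 ± 0.57, 0.00678; at least 3.37-fold), DM00260P2 (−1.54 ± 0.36, 0.00619) and DM01774P1 (−1.41 ± 0.37, 0.0118) fell. DM01556P2, also a vitellogenin fused with superoxide dismutase, had 0.45 ± 0.81 (adjusted p = 0.767). Of 21 cytosolic ribosomal protein features, 18 fell and none rose (median −1.26), among them P1 (DM02018P1, −2.07, adjusted p = 0.000985), S6 (DM01833P1, −1.67, 0.000591; at least 2.63-fold) and L9e (DM01592P3, −1.67, 0.000364). Outside that list, ribosomal proteins S25e (DM01989P3, −2.71 ± 0.41, adjusted p = 0.000324) and P2-like (DM02189P2, −2.71 ± 0.35, 0.000103) fell too. Of 13 muscle and cytoskeleton features, 12 fell (median −1.36), including nonmuscle myosin (DM02391P3, −1.90, adjusted p = 7.15e-05), myosin isoform B (DM02533P1, −1.78, 0.000734; at least 2.34-fold) and paramyosin (DM02599P2, −1.36, 0.000253). The sarcoplasmic calcium pump listed as calcium ATPase at 60A (DM00307P3), outside that list, fell by 1.97 (adjusted p = 0.000978). Tumor protein, translationally-controlled (DM01720P1), a growth-linked protein, fell by 2.81 (adjusted p = 0.000405). With camera and a preset correlation the ribosomal list gave adjusted p = 0.00134 and the muscle list 0.00291, but both gave adjusted p = 0.609 with an estimated correlation, and the vitellogenin list gave 0.0835. With median centring the muscle median was −0.89. The gene lists here and below hold only features the authors selected on these samples, and may leave out other features of a family. Their counts are therefore not shares of all such features on the array. Of the 434 features with a significant match, 212 passed in Ag+ in either direction. In L-SiO2-NW 14 passed, in S-PVP-NW 29 and in S-SiO2-NW 73.

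Compound eye opsin (DM02717P2), a visual pigment, rose by 2.13 ± 0.52 (adjusted p = 0.0075; 1216 ± 908 against 159 ± 55), 4-aminobutyrate aminotransferase (DM00932P3), which breaks down the transmitter GABA, by 1.88 ± 0.38 (0.00224; dim on 3 Control arrays, at least 2.36-fold), and the ryanodine receptor (DM00540P2), a calcium release channel, by 1.65 (0.000364). Angiotensin-converting enzyme (DM01048P1) rose by 1.48 ± 0.28 (adjusted p = 0.00135), a LDLa domain containing chitin-binding protein (DM00251P1) by 1.77 (0.00188), helmsman (DM00005P1) by 1.74 (0.00194) and a HECT, UBA and WWE domain ubiquitin ligase (DM00630P4) by 1.56 (0.00339). The carnitine carrier Slc25a20 (DM02071P1) fell by 2.08 (adjusted p = 0.00594), hemoglobin DM01561P3 by 2.40 ± 0.75 (0.034), hemoglobin DM01948P1 by 0.92 ± 0.31 (0.0419; at least 1.2-fold), and cuticular protein 50Cb (DM02582P1) fell by 2.12 (0.0456). Ag+ 2 had no value for hemoglobin DM01561P3 or for DM01720P1, so their falls rest on the other Ag+ arrays. Arrestin 2 (DM01248P1), a partner of opsin, had 0.91 (adjusted p = 0.0754). From the Ag+ and Control arrays alone, opsin (adjusted p = 0.0557), 4-aminobutyrate aminotransferase (0.0616) and hemoglobin DM01561P3 (0.0998) did not pass. With median centring, hemoglobins DM01561P3 (adjusted p = 0.101) and DM01948P1 (0.058), cuticular protein 50Cb (0.153) and vitellogenin DM02255P1 (0.0547) did not pass.

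Over all features 1478 rose and 1079 fell in Ag+ (limma, n = 4 per group), 2557 in total, of which 823 carry an entry in the authors' table, 212 a significant database match and 136 a gene name. More than 2-fold differences made up 634 of them. The total was 1734 without Ag+ 3, 1629 from the Ag+ and Control arrays alone, and 1471 with the array floor as a covariate. Direction depended on scaling: 57.8% were rises, against 74.9% with median centring, 50.5% with a common 75th percentile and 24.7% with that percentile taken over bright features.

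**Figure D2:**
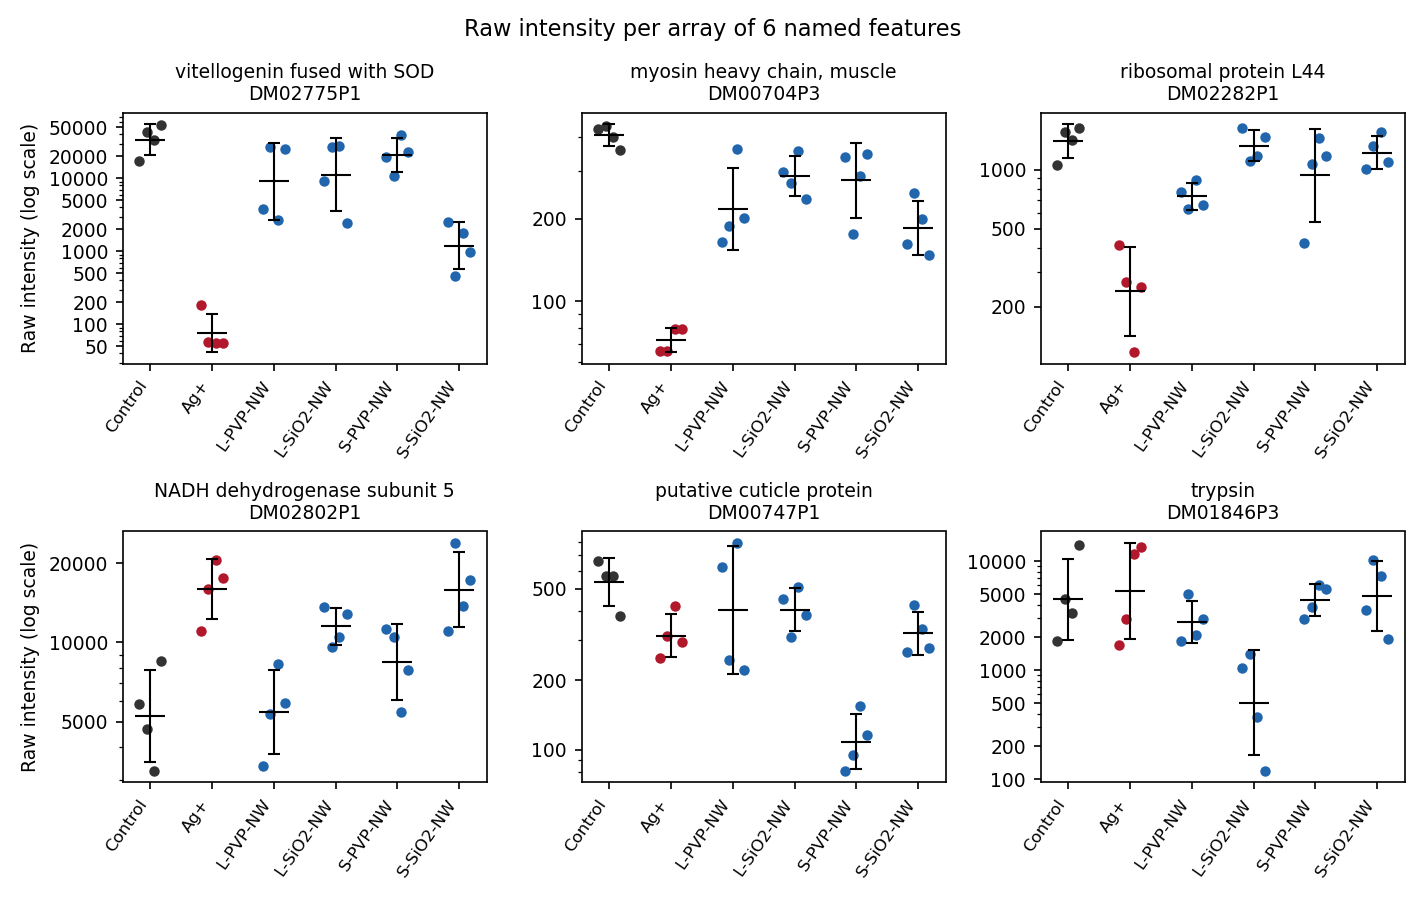
Intensity of 6 named features on each array, with Control in grey, Ag+ in red and nanowires in blue. Bars give the geometric mean ± 1 SD of log10 intensity (n = 4 arrays per group).

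No named gene differed from Control in L-PVP-NW. Vitellogenin features had values below 0 that did not pass: DM01546P3 −1.85 (adjusted p = 0.322), DM02255P1 −1.74 (0.427), DM01857P2 −1.70 (0.482), DM02775P1 −1.69 ± 0.89 (0.597) and DM01774P1 −1.12 (0.322). Collagen (DM00693P2), a matrix protein, had −0.51 (adjusted p = 0.139), a putative defense protein (DM02004P1) −0.60 (0.193) and the starch-digesting alpha-amylase (DM01845P3) 0.59 (0.206). Fatty acid binding protein (DM02721P1), which carries lipids within cells, had −1.71 (adjusted p = 0.452).

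The vitellogenin list had a median of −1.29 in L-PVP-NW (camera adjusted p = 0.00134, or 0.609 with an estimated correlation). However, none of its 10 features passed over all features and 2 fell when adjusted over the list alone. The fall was uneven: list scores on replicates A to D were 0.29, −0.536, −1.702 and 0.498, against 0.593 to 1.581 in Control. The oxidative stress list had −0.93 (adjusted p = 0.00736; 0.609 with an estimated correlation), none passing, and 8 of its 11 members are vitellogenin features. Only 4 features rose and 0 fell in L-PVP-NW (limma, n = 4 per group; 1331 at unadjusted p under 0.05), all without a gene name: DM04057P3 by 6.03 ± 0.61 (adjusted p = 7.44e-05; at least 50.2-fold), DM11644P3 by 5.95 ± 0.71 (0.000429; at least 31.7-fold), DM12580P3 by 1.49 ± 0.25 (0.0307; at least 1.75-fold) and DM05091P2 by 0.56 ± 0.09 (0.017). The first 2 were dim on all 4 Control arrays and DM12580P3 on 3, and DM05091P2 was dim in both groups (78 ± 14.3 against 52 ± 4.83). These 4 were chosen after values were seen. The count of 4 was 2 without Control 4, 123 without Control 1, 85 without L-PVP-NW D, 24 with array weights and 0 from the 8 arrays of both groups alone.

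Of 19 digestive enzyme features 2 proteases fell in L-SiO2-NW. Trypsin (DM01846P3) fell by 3.48 ± 0.82 (SE, n = 4 per group; adjusted p = 0.0454; 734.2 ± 591 against 5978 ± 5560) and chymotrypsin (DM02109P1) fell by 3.12 ± 0.67 (0.0362; 379.8 ± 256 against 3364 ± 3940); both enzymes split food protein in the gut. Control 4 stood apart with a digestive enzyme score of 1.049, where the other Control arrays had −0.076 to 0.05. Salivary secreted protein (DM02156P3) fell by 2.60 (adjusted p = 0.0387), plasminogen (DM01450P1) by 1.07 (0.00645; at least 1.26-fold) and a vacuolar proton ATPase (DM00795P1), which acidifies compartments and whose database match is in the alga Ostreococcus tauri, by 0.79 (0.0387). Tyrosine 3-monooxygenase (DM00246P1), the first enzyme of catecholamine synthesis, rose by 0.75 (adjusted p = 0.0182; 116.2 ± 16.4 against 65.5 ± 13.7, dim in Control) and ubiquitin-conjugating enzyme h (DM00219P2) by 0.91 (0.0417). Carboxypeptidase B (DM01830P1) had −2.40 (adjusted p = 0.121), hemoglobin 4 (DM01998P1) −2.40 ± 0.62 (0.0666) and ribosomal protein P1 −1.46 (0.0634).

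The digestive enzyme list of 19 features had a median of −0.46 in L-SiO2-NW, with those 2 falling over all features and 5 when adjusted over the list alone (camera, adjusted p = 0.00736; 0.609 with an estimated correlation). Ribosomal proteins had a median of −0.49 (adjusted p = 0.0279; 0.691 with an estimated correlation), with 0 past over all features and 9 over the list, and the muscle list −0.53 (0.034; 0.648 with an estimated correlation), with 0 and 7. With median centring the ribosomal median was 0 and the muscle median −0.21. In total 85 features rose and 53 fell (limma, n = 4 per group), 138 together, of which 8 are named; 61.6% were rises, against 76.9% with median centring, 43.8% with a common 75th percentile and 42.9% over bright features. The 138 became 18 without Control 2, 25 without Control 3, 427 without Control 4, 59 without L-SiO2-NW 1, 83 without L-SiO2-NW 2, 19 without L-SiO2-NW 4, 2 from the 8 arrays alone, where trypsin and chymotrypsin did not pass, and 0 with the array floor as a covariate.

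Cuticle transcripts fell in S-PVP-NW. A putative cuticle protein (DM00747P1), part of the chitin-based exoskeleton, fell by 2.62 ± 0.34 (SE, n = 4 per group; adjusted p = 0.000515; 111.8 ± 32.2 against 546 ± 119), cuticular protein 50Cb fell by 3.14 (0.0298), cuticle protein DM02274P1 by 2.00 (0.00996) and cuticular protein 146 of the RR-2 family (DM02211P2) by 1.97 (0.0298). The Spätzle 2-like protein (DM01743P3), of the family of Toll receptor ligands, fell by 2.49 ± 0.31 (adjusted p = 0.000458; 1980 ± 1030 against 9487 ± 3180), Slc25a20 by 3.15 ± 0.49 (0.00201; 377.5 ± 197 against 2527 ± 1100), dynein light chain 2 (DM01147P4) by 2.38 (0.00534) and a haem peroxidase (DM01544P2) fell by 2.17 (0.0114). Vitellogenin DM00260P2 fell by 1.47 ± 0.36 (adjusted p = 0.0496), while DM01857P2 had −2.70 (0.0726), DM02255P1 −2.51 (0.0726) and DM01546P3 −2.24 (0.0723). No named feature rose.

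Of 15 cuticle features, 7 fell over all features and 11 when adjusted over the list alone, with a median of −1.61 (camera, adjusted p = 0.000834; 0.609 with an estimated correlation). Cuticle falls were not limited to S-PVP-NW: DM00747P1 fell in Ag+ by 1.28 (adjusted p = 0.0133) and in S-SiO2-NW by 1.42 (0.0266), and DM02274P1 fell by 1.51 (0.0108) and DM02211P2 fell by 1.38 (0.0381) in Ag+. Of 35 features with any cuticle match, 14 fell in Ag+, 21 in S-PVP-NW and 10 in S-SiO2-NW. The vitellogenin list had a median of −1.58 (adjusted p = 0.0103; 0.609 with an estimated correlation), with 1 fall over all features and 7 over the list, and the oxidative stress list −1.47 (0.0547). In S-PVP-NW 41 features rose and 153 fell (limma, n = 4 per group), 194 together, of which 17 are named; 21.1% were rises, against 68.5% with median centring, 39.5% with a common 75th percentile and 9% over bright features. The 194 became 104 without Control 3, 309 without Control 4, 115 without S-PVP-NW 1, 104 without S-PVP-NW 2, 98 from the 8 arrays alone and 1, none of the genes above, with the array floor as a covariate.

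In S-SiO2-NW 1 yolk feature and several muscle and ribosomal transcripts fell. Vitellogenin DM02775P1 fell by 5 ± 0.89 (SE, n = 4 per group; adjusted p = 0.00643; 1439 ± 908), muscle myosin DM00704P3 by 1.73 ± 0.27 (0.00407; 189.2 ± 44.7), vacuolar proton ATPase by 1.26 (0.00303; dim, 83.5 ± 12.4 against 161.2 ± 19.1), nonmuscle myosin DM01615P1 by 1.24 (0.0389), beta actin by 1.10 (0.0416) and muscle protein 20 by 1.03 (0.0299). No other vitellogenin feature fell, and DM01556P2 had 1.77 (adjusted p = 0.217). Among ribosomal proteins P1 fell by 1.59 (adjusted p = 0.0233), L18 by 1.13 (0.0314), L7 by 1.12 (0.0314) and L10a by 0.99 (0.0153). A 10 kDa secreted protein (DM02000P3) rose by 1.82 ± 0.43 (adjusted p = 0.0234; 34340 ± 5610 against 9602 ± 5570), mitochondrial NADH dehydrogenase subunit 5 by 1.27 ± 0.26 (0.0131), the redox enzyme thioredoxin reductase 1 (DM00670P2) by 1.13 (0.025), ubiquitin-conjugating enzyme h by 1.02 (0.0125) and the ryanodine receptor by 0.95 (0.0417). Inositol-making myo-inositol 1-phosphate synthase (DM00955P3) rose by 0.80 (adjusted p = 0.025; at least 1.22-fold) and the Wnt receptor frizzled 7b by 0.70 (0.0131; 138.2 ± 40.1 against 68 ± 7.79, dim in Control).

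Ribosomal features had a median of −0.81 in S-SiO2-NW, 7 of 21 falling over all features and 16 when adjusted over the list alone (camera, adjusted p = 0.00291; 0.609 with an estimated correlation). The muscle list had −0.64, with 5 of 13 falling and 10 over the list (adjusted p = 0.00904; 0.609 with an estimated correlation). With median centring these medians were −0.21 and −0.30. In total 404 features rose and 275 fell (limma, n = 4 per group), 679 together, of which 41 are named; 59.5% were rises, against 81.9% with median centring, 11.2% with a common 75th percentile and 34.5% over bright features. The 679 became 272 without Control 1, 281 without Control 2, 182 without Control 3, 1120 without Control 4, 344 without S-SiO2-NW 1, 425 without S-SiO2-NW 3, 256 without S-SiO2-NW 4, 4 from the 8 arrays alone, none of the genes above among them, and 0 with the array floor as a covariate.

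**Figure D3:**
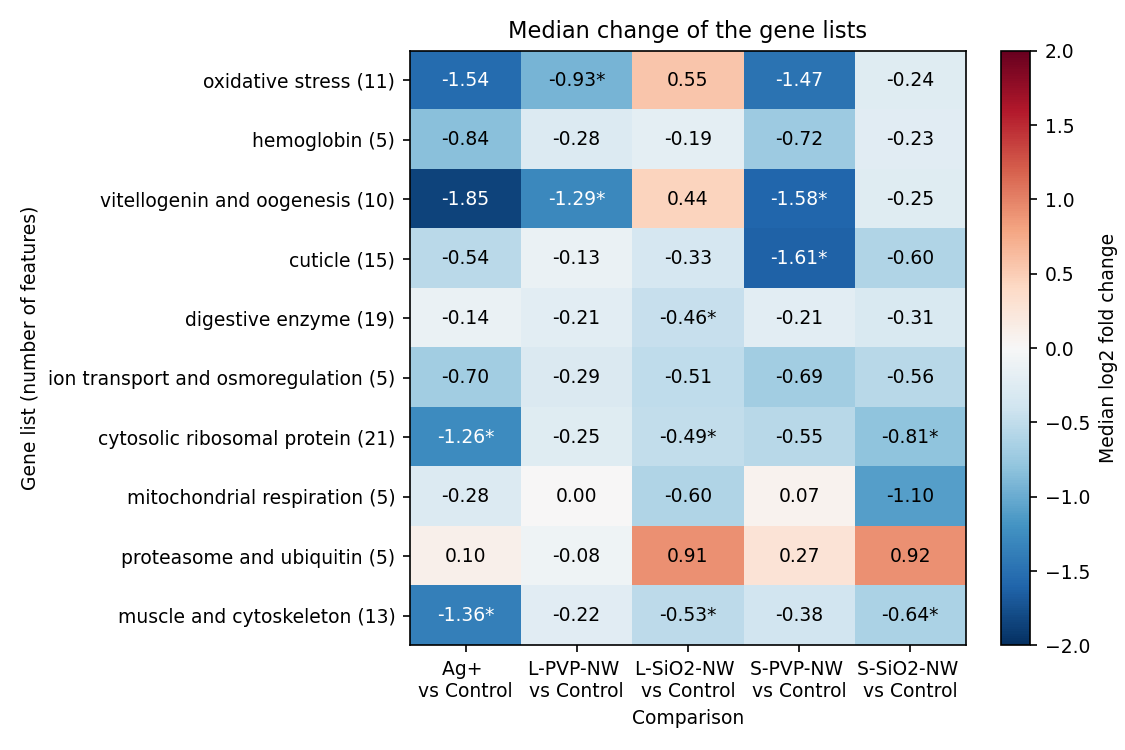
Median log2 difference from Control of 10 gene lists in 5 exposures. An asterisk stands for a camera adjusted p under 0.05 with the preset correlation.

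Set against Ag+ directly, all 4 nanowires had more of vitellogenin DM02775P1, which other yolk features did not share throughout. Vitellogenin DM02775P1 was higher by 6.82 ± 0.89 in L-PVP-NW (n = 4 per group; adjusted p = 0.000272), by 6.90 in L-SiO2-NW (0.00017), by 7.67 in S-PVP-NW (9.12e-05) and by 3.52 ± 0.89 in S-SiO2-NW (0.0399); with Ag+ dim these are at least 75.7-fold, 79.8-fold, 136-fold and 7.67-fold. Against Control, vitellogenin DM02255P1 had −2.51 in S-PVP-NW and −2.47 in Ag+, and DM01857P2 had −2.70 and −2.17. In L-SiO2-NW other yolk features were also higher than in Ag+: DM00260P2 by 1.86 (at least 3.49-fold) and DM01774P1 by 1.58 (at least 2.63-fold). Ribosomal protein S25e was higher than in Ag+ by 2.43 ± 0.41 in L-PVP-NW (adjusted p = 0.00129), 2.79 in S-PVP-NW (0.000481) and 2.42 in S-SiO2-NW (0.00364), and L44 by 2.38 ± 0.34 in L-SiO2-NW (0.000363). The 10 kDa secreted protein was higher by 2.67 ± 0.43 in L-PVP-NW (adjusted p = 0.00106) and 3.52 ± 0.43 in S-SiO2-NW (0.000208), and hemoglobin DM01561P3 by 2.48 ± 0.75 in L-PVP-NW (0.0323) and 3.40 ± 0.75 in L-SiO2-NW (0.00962).

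A papain family cysteine protease (DM02974P1) was lower than in Ag+ in every nanowire group: by −3.22 ± 0.85 in L-PVP-NW (adjusted p = 0.0157), −4.14 ± 0.85 in L-SiO2-NW (0.00532), −3.44 in S-PVP-NW (0.0133) and −3.47 ± 0.85 in S-SiO2-NW (0.0333). Against Control it rose in Ag+ by 3.48 ± 0.85 (adjusted p = 0.00777; 4408 ± 3830 against 335.2 ± 432, with overlap between the arrays), and the nanowires had 0.26, −0.67, 0.04 and 0.01. In L-SiO2-NW chymotrypsin (−3.87 ± 0.67, adjusted p = 0.00157), trypsin (−3.61 ± 0.82, 0.0104), carboxypeptidase B (DM00410P1, −3.05 ± 0.51, 0.00119) and hemoglobin 4 (−3.01 ± 0.62, 0.00553) were lower too; carboxypeptidase B DM00410P1 rose in Ag+ by 1.82 ± 0.51 against Control (0.018). Cytochrome c oxidase subunit I had −1.97 in L-PVP-NW (adjusted p = 0.00394) and opsin −1.89 (0.019), fatty acid binding protein had −2.29 ± 0.68 (0.0288), and angiotensin-converting enzyme had −1.15 ± 0.28 in S-SiO2-NW (0.0309). In S-PVP-NW haem peroxidase (−2.50 ± 0.43, adjusted p = 0.00125) and the Spätzle 2-like protein (−2.06 ± 0.31, 0.000572) were lower than in Ag+.

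Against Ag+, limma gave 1005 features higher and 1229 lower in L-PVP-NW, 444 and 638 in L-SiO2-NW, 839 and 813 in S-PVP-NW, and 199 and 178 in S-SiO2-NW. Named features among them numbered 104, 62, 77 and 21. The L-PVP-NW total of 2234 was 1172 without Ag+ 3, 1232 without Ag+ 4, 1263 without L-PVP-NW A, 1214 without L-PVP-NW B and 29 with the array floor as a covariate; the L-SiO2-NW total of 1082 was 580 without Ag+ 3, 688 without Ag+ 4, 619 without L-SiO2-NW 2, 639 without L-SiO2-NW 3 and 339 with the floor. The S-PVP-NW total of 1652 was 797 without Ag+ 3, 904 without Ag+ 4, 912 without S-PVP-NW 1, 999 without S-PVP-NW 4 and 1080 with the floor; the S-SiO2-NW total of 377 was 699 without Ag+ 1, 218 without Ag+ 2, 148 without Ag+ 3, 159 without Ag+ 4, 200 without S-SiO2-NW 2, 191 without S-SiO2-NW 3 and 43 from the 8 arrays alone. Percent higher was 45 in L-PVP-NW (26.6 with median centring, 57.7 with a common 75th percentile, 73.5 over bright features), 41 in L-SiO2-NW (42.5, 33.6, 71.4), 50.8 in S-PVP-NW (55, 51.2, 75) and 52.8 in S-SiO2-NW (74.9, 42.4, 82.4).

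Vitellogenin DM02775P1 was lower with silica than with PVP, against the direction of the other vitellogenin features. Against Control, those others had higher values in both silica groups than in both PVP groups. For example, DM02255P1 had 1.08 and 0.31 in L-SiO2-NW and S-SiO2-NW, and −1.74 and −2.51 in L-PVP-NW and S-PVP-NW. The vitelline membrane feature DM02106P1 did not share this, and the list was not tested for coating. Averaged over length, SiO2 minus PVP was 3.41 ± 0.57 for vitellogenin DM01556P2 (n = 8 arrays per coating; adjusted p = 0.00191) and 1.19 ± 0.26 for DM01774P1 (0.00777), but −2.04 ± 0.63 for DM02775P1 (0.0449). For DM02775P1 the difference was −4.15 ± 0.89 among short nanowires (adjusted p = 0.0339) and 0.08 ± 0.89 among long ones (0.979), but the interaction of 4.22 ± 1.26 did not pass (0.402). Fatty acid binding protein had 1.74 ± 0.48 (adjusted p = 0.0268), cuticular protein 77 of the RR-1 family (DM02191P2) 1.70 ± 0.40 (0.0123) and chitinase (DM00651P1), which degrades chitin at moult, 1.15 ± 0.25 (0.0082). Lower with silica were the respiratory-chain subunit ubiquinol-cytochrome c reductase 14 kD (DM02249P3, −1.19 ± 0.30, adjusted p = 0.016), glycoprotein 25l (−1.65 ± 0.43, 0.0201) and ribosomal protein P1 (−0.89, 0.0353).

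By coating, 768 features were higher and 695 lower with silica (limma), 1463 together, 61 of them named; 52.5% were higher, against 61.6% with median centring, 10.3% with a common 75th percentile and 50.6% over bright features. Without L-PVP-NW B the total was 873, without S-PVP-NW 4 it was 965, and with the array floor as a covariate it was 12. Among long nanowires SiO2 and PVP differed for 686 features (385 higher, 301 lower), and among short ones for 129 (67 higher, 62 lower). The long total was 255 without L-PVP-NW A, 204 without L-PVP-NW B, 316 without L-SiO2-NW 1, 282 without L-SiO2-NW 4 and 0 with the floor; the short total was 22 without S-PVP-NW 1, 72 without S-PVP-NW 3, 5 without S-PVP-NW 4, 73 without S-SiO2-NW 1, 19 without S-SiO2-NW 2 and 3 without S-SiO2-NW 3. Percent higher was 56.1 among long nanowires (61.2 with median centring, 8.8 with a common 75th percentile, 62.9 over bright features) and 51.9 among short ones (59.7, 45.8, 52.5).

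Several genes that fell in S-PVP-NW were higher with long than with short nanowires. Long minus short was 1.72 ± 0.30 for haem peroxidase (n = 8 arrays per length; adjusted p = 0.017), 1.51 ± 0.22 for the Spätzle 2-like protein (0.00926), 1.53 ± 0.35 for Slc25a20 (0.0369), 1.31 ± 0.24 for cuticle protein DM00747P1 (0.0184) and 1.25 ± 0.30 for dynein light chain 2 (0.0437). Cuticle protein DM02274P1 had 1.21 ± 0.28 (adjusted p = 0.0374), while 50Cb (DM02582P1) had 1.85 ± 0.51 (0.0753) and cuticular protein 146 (DM02211P2) 1.19 ± 0.32 (0.067). Within coatings, the Spätzle 2-like protein (DM01743P3) had 2.50 ± 0.31 with PVP (adjusted p = 0.000593) and 0.51 ± 0.31 with SiO2 (0.985), and cuticle protein DM00747P1 2.13 ± 0.34 (0.00423) and 0.48 ± 0.34 (0.992). Chymotrypsin had −1.96 ± 0.48 (adjusted p = 0.0463), myo-inositol 1-phosphate synthase −0.61 (0.0334) and frizzled 7b −0.42 (0.0495).

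By length, 111 features were higher and 82 lower in long nanowires (limma), 193 together, 13 of them named; 57.5% were higher, against 23% with median centring, 50.7% with a common 75th percentile and 66.9% over bright features. The 193 became 42 without L-PVP-NW A, 98 without L-PVP-NW B, 70 without L-SiO2-NW 2, 47 without L-SiO2-NW 3, 96, 55, 81 and 124 without S-PVP-NW 1, 2, 3 and 4, 120, 120 and 54 without S-SiO2-NW 1, 2 and 3, and 0 with the array floor as a covariate. Among PVP nanowires length gave 195 higher and 113 lower, 308 together: 67, 89, 200 and 480 without L-PVP-NW A, B, C and D, 151, 106, 107 and 154 without S-PVP-NW 1, 2, 3 and 4, and 0 with the floor. Among SiO2 nanowires it gave 1 higher and 4 lower, 5 together (825 at unadjusted p under 0.05): 2, 14, 0 and 1 without L-SiO2-NW 1, 2, 3 and 4, 0, 0 and 24 without S-SiO2-NW 2, 3 and 4, and 0 from the 8 arrays alone. Percent higher was 63.3 among PVP nanowires (27.9 with median centring, 55.9 with a common 75th percentile, 72.5 over bright features) and 20 among SiO2 nanowires (25, 5.9, 14.3).

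No named gene passed the test for an effect of coating that depends on length. The 10 kDa secreted protein had −3.14 ± 0.60 (n = 4 per group; adjusted p = 0.0757), the Spätzle 2-like protein −1.99 ± 0.44 (0.173) and the actin-binding transgelin (DM01598P3) −1.57 ± 0.42 (0.326). Unnamed features chosen after values were seen passed: DM04057P3 (−6.09 ± 0.87, adjusted p = 0.0135), DM11644P3 (−5.92 ± 1.00, 0.0435) and DM12737P2 (−1.46 ± 0.24, 0.0435). Long minus short was 6.39 with PVP and 0.30 with SiO2 for DM04057P3, 5.86 and −0.06 for DM11644P3, and 0.83 and −0.63 for DM12737P2. The 3 features in total (limma; 1105 at unadjusted p under 0.05) became 33 without L-PVP-NW D, 0 without S-PVP-NW 2, S-PVP-NW 3 or S-SiO2-NW 2, and 0 with the array floor as a covariate.

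**Figure D4:**
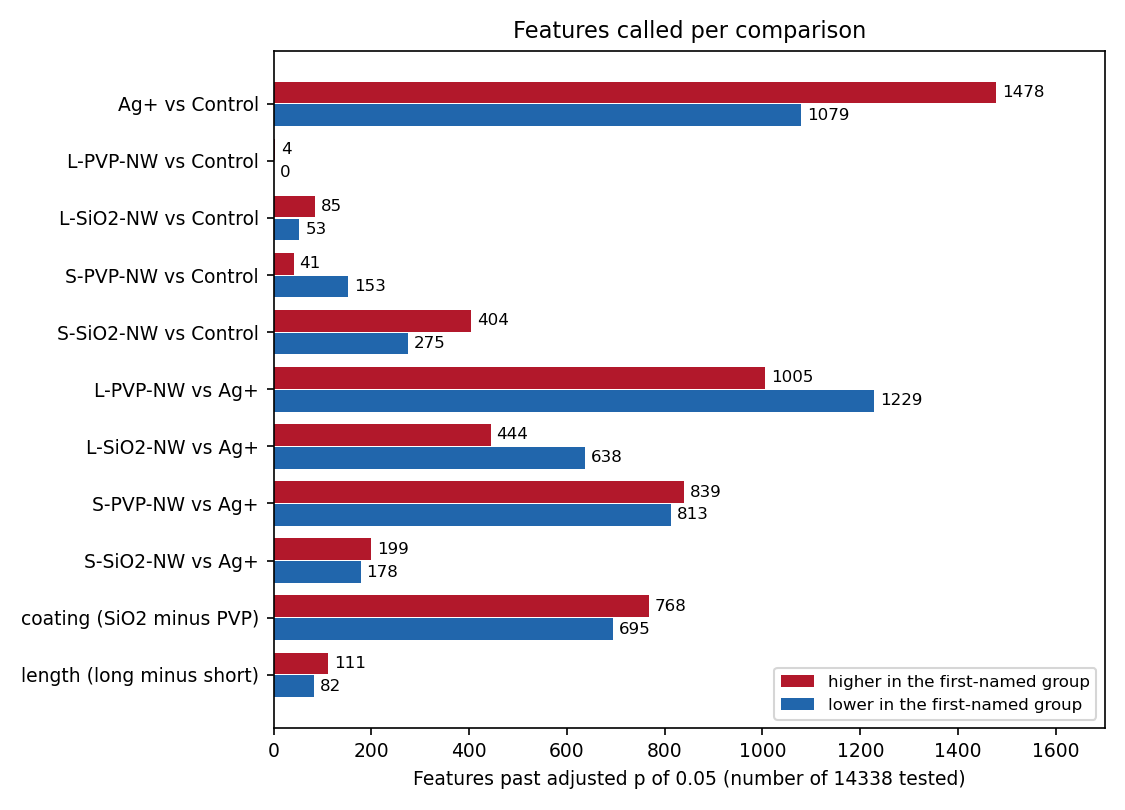
Features higher and lower in each comparison (limma, adjusted p under 0.05 over 14338 features, n = 4 arrays per group).

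Several pairs of exposures shared more features than independent lists would give, although the expected numbers take no account of the shared Control. L-PVP-NW, with only 4 features, shared 0 with the other nanowires and 1 with Ag+ (0.412 expected). Features shared by Ag+ and S-SiO2-NW include vitellogenin DM02775P1, muscle myosin DM00704P3, ribosomal protein P1, NADH dehydrogenase subunit 5 and the ryanodine receptor, each in the same direction. In total 302 features rose in both Ag+ and S-SiO2-NW (41.6 expected) and 202 fell in both (20.7 expected), with 3 in opposite directions. L-SiO2-NW and S-SiO2-NW shared 63 rises (2.4 expected) and 27 falls (1.02), S-PVP-NW and S-SiO2-NW 23 (1.16) and 59 (2.93), Ag+ and S-PVP-NW 29 (4.23) and 63 (11.5), Ag+ and L-SiO2-NW 58 (8.76) and 24 (3.99), and L-SiO2-NW and S-PVP-NW 2 (0.243) and 12 (0.566). Only 9 features passed in Ag+, L-SiO2-NW, S-PVP-NW and S-SiO2-NW together, 1 rising and 8 falling, none named.

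A shared Control raises these overlaps by itself: correlations of log2 differences simulated with a shared Control gave 0.5 and a covariance of 0.0325. Ag+ and S-SiO2-NW had r = 0.69 across features and a covariance of 0.142, and r = 0.43 when each exposure was set against separate Control arrays. L-SiO2-NW and S-SiO2-NW had 0.70, 0.0975 and 0.34, S-PVP-NW and S-SiO2-NW 0.56, 0.0851 and 0.25, Ag+ and L-SiO2-NW 0.48, 0.0908 and 0.23, Ag+ and S-PVP-NW 0.45, 0.0923 and 0.22, Ag+ and L-PVP-NW 0.41, 0.0633 and 0.14, L-SiO2-NW and S-PVP-NW 0.41, 0.0585 and 0.11, and L-PVP-NW and S-PVP-NW 0.44, 0.0506 and 0.09. For L-PVP-NW the values with L-SiO2-NW were 0.32, 0.0335 and −0.03, and with S-SiO2-NW 0.28, 0.0315 and −0.03, so no excess over a shared Control was seen for those 2 pairs. Mean array floors differed from Control by −1.75 in Ag+, −5.75 in L-SiO2-NW, −5.25 in S-PVP-NW and −3.91 in S-SiO2-NW, but by 1.25 in L-PVP-NW. Splitting the Control arrays cannot remove a background shift that exposures share. An excess in the other pairs therefore cannot be told apart from such a shift. All 4 exposed values lay outside all 4 Control values for 18.82% of features in Ag+, 3.4% in L-PVP-NW, 8.89% in L-SiO2-NW, 8.75% in S-PVP-NW and 10.74% in S-SiO2-NW, where chance gives 2.86%.

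The authors' deposited table lists log2 ratios for chosen features, among them vitellogenin DM02775P1 at −9.5 in Ag+, vitellogenin DM01546P3 at −2.9, muscle myosin DM00704P3 at −3.1 and ribosomal protein L44 at −3.1; the fit here gave −8.51, −2.72, −2.72 and −2.95. It holds 690 features for Ag+ (180 up, 510 down), 277 for L-PVP-NW (143, 134), 519 for L-SiO2-NW (212, 307), 623 for S-PVP-NW (121, 502) and 562 for S-SiO2-NW (182, 380). Across listed features the correlation with the log2 differences here was 0.987, 0.962, 0.979, 0.975 and 0.982, every sign the same. Of the listed features 564 (81.7%), 4 (1.4%), 74 (14.3%), 156 (25%) and 264 (47%) passed here. Both sets of values come from the same arrays, and gene names and lists here rest on features the authors selected on these samples, so neither the match nor the list results are independent evidence.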

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

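Chosen only after the result was seen were the tests of a background difference between groups, of a spot defect, of an equal fall of all vitellogenin transcripts, and of the lower array floor behind the cuticle result. Of 366 groups of 4 arrays looked at, 13 (3.6%) held an array far from the other 3, where chance gives about 1 in 20. The groups include those of 48 features picked for passing with no overlap between exposed and Control arrays. The share of 1 in 20 is therefore no clear baseline.

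Single arrays far from their group concerned named genes and lists, with the gap given as a share of the group's range. Control 4 stood apart for the oxidative stress score (0.852; 1.376, next 0.57), the cuticle score (0.899, low), the digestive enzyme score (0.888; 1.049, next 0.05), 4-aminobutyrate aminotransferase (0.93, high) and peptidyl-prolyl cis-trans isomerase E (0.881, low). Control 1 did for opsin (0.87, low) and the 10 kDa secreted protein (0.928, high). Ag+ 1 did for vitellogenin DM02775P1 (0.97, high), S-PVP-NW 1 for tyrosine 3-monooxygenase (0.838, high), S-PVP-NW 2 for ribosomal protein P2-like (0.902, low) and L-PVP-NW A for UTP14 (0.831, high). In array quality, Ag+ 3 had a 1st percentile of 45 where the others had 46 (1) and L-PVP-NW C had 4528 features above the dim limit, next 3644 (0.873).

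A difference between groups came from the interaction of coating and length: DM04057P3 (−6.09), DM11644P3 (−5.92) and DM12737P2 (−1.46), each without a gene name. Both larger values come from high intensities in L-PVP-NW alone.

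Exchanging arrays between groups gave at least as many features as the real grouping in 1 of 35 splits (the real one) for Ag+ (2557, next 1245), L-SiO2-NW (138, next 11), S-PVP-NW (194, next 4) and S-SiO2-NW (679, next 21) against Control. The same held against Ag+ for L-PVP-NW (2234, next 836), L-SiO2-NW (1082, next 4), S-PVP-NW (1652, next 2) and S-SiO2-NW (377, next 299), and for coating among long (686, next 3) and short nanowires (129, next 69) and length with PVP (308, next 1). In 1 of 100 splits it held for coating (1463, next 2), length (193, next 105) and any difference (3203, next 63). For the interaction it held in 3 of 100 (3 features, highest 375). The splits for coating, length and the interaction mix both coatings and lengths, whose differences then add to the spread and can lower the counts. This test therefore cannot exclude chance for length or for the 3 features of the interaction. For coating the same limit holds, but the splits within long and within short nanowires above do not mix lengths. Chance is not excluded for L-PVP-NW against Control (6 of 35 splits; 4 features, highest 235), for length with SiO2 (2 of 35; 5 features, highest 184) or for the number of gene list results (31 of 100; 11 results, highest 18). The split with 235 sets Control 1 with L-PVP-NW A, B and C against the rest, which shows a structure among these 8 arrays larger than the exposure.

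Ag+ changed 2557 features and L-PVP-NW 4, at doses matched to toxicity. Counts did not follow the floor alone: S-SiO2-NW had 679 features with a floor 3.91 units below Control, while Ag+ was only 1.75 below. A background difference is not excluded, since the floors of L-PVP-NW and Ag+ are separated. With the array floor as a covariate, their direct comparison went from 2234 features to 29. The mean residual variance of L-PVP-NW was 0.76 times that of Ag+, but the median went the other way (0.0188 against 0.0178). The fit pools the spread over all groups, so a group's own spread does not by itself set its count. These values therefore cannot decide whether a larger spread between L-PVP-NW arrays contributes, and that stays open. Variation of background within groups cannot be told apart as a contributor, since 1471 features were left with the array floor as a covariate. More dissolved silver reaching tissue in Ag+ may explain the gap but stays untested, because silver mass and uptake were not analysed here.

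Vitellogenin DM02775P1 fell by 8.51 log2 units in Ag+ while the other 7 vitellogenin-superoxide dismutase features had a median of −2.17 (−2.72 to 0.45). All 4 Ag+ arrays (55 to 184) lay below the lowest Control array (17536), and all 4 Control arrays (17536 to 53310) above every Ag+ and S-SiO2-NW array (464 to 2526). These intensities argue against a spot defect or a Control level raised on single arrays, as do 2431 to 39258 on the 12 arrays of L-PVP-NW, L-SiO2-NW and S-PVP-NW. The gap to the median of the others in Ag+ was −7.12 standard errors, but the feature was picked for its large fall there, so this restates the pick in part. An equal fall of all vitellogenin transcripts is argued against by S-SiO2-NW, which shares the Control arrays but was not used for the pick. There the feature fell by 5 ± 0.89 and the other 7 had −0.91 to 1.77. A gene copy that responds more strongly, or a difference in ovary stage between the groups, could produce the gap between this feature and the others and was not tested.

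Cuticle features had a median of −1.61 in S-PVP-NW. The 10 members with a Control intensity over 200 had a median of −1.98. They too carry names because the authors listed them as changed on these arrays. A limit on Control intensity alone also favours a fall. These members therefore cannot decide whether the lower floor of the S-PVP-NW arrays contributes, and that stays open. All 35 features with any cuticle match had a median of −1.51 with 21 falling, but they carry names because the authors listed them as changed on these arrays, so the limit set beforehand was no test and a fall of single members stays open. With the floor as a covariate no cuticle feature named here passed: DM00747P1 had −2.68 (adjusted p = 0.204) after −2.62 ± 0.34, and 50Cb −1.73 (0.758) after −3.14, with the median SE over features 1.8 times larger. Moult stage could differ between the groups, and a slide or scan batch of the S-PVP-NW arrays could too; both stay open as untested.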

How the results depend on the processing

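Alternatives chosen only after values were seen were both scalings to a common 75th percentile, the residual component, the array floor, the limit on mean intensity, and a background of all features for lists. No named value that passed changed direction in the settings listed next. Of 131 named values past the test, quantile normalization without background correction and the residual component each lost 0. Both outcomes were nearly fixed in advance and are no sign of robustness. The component is taken from differences from the group means, so it leaves the log2 differences in place and lowers the spread. The background correction keeps the order of features within an array, on which quantile normalization rests. The 75th percentile of raw values lost 7 and that over bright features 7. Median centring lost 20, a fit of only the arrays compared 61 and the array floor 79. With each array left out in turn, 286 of 1192 cases were lost, over 56 of the named values. Over all settings and the 211 named values, a value that passed in neither fit had the other sign 51 times. The cause of these shifts was not tested. Relative to all features, the 75th percentile of raw values put the median log2 difference at −0.28 in Ag+, 0.03 in L-PVP-NW, −0.39 in L-SiO2-NW, −0.26 in S-PVP-NW, −0.47 in S-SiO2-NW, −0.32 for coating and 0.18 for length, and that over bright features at −0.11 in Ag+. Leaving out the lowest part of the features, or features with a missing value, moved no count by more than 1.5 times.

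Fitting only the arrays compared, where fewer arrays estimate the spread, gave 1629 features for Ag+ against Control (2557 over all 24 arrays), 0 for L-PVP-NW (4), 2 for L-SiO2-NW (138), 98 for S-PVP-NW (194), 4 for S-SiO2-NW (679), 648 for L-SiO2-NW against Ag+ (1082), 43 for S-SiO2-NW against Ag+ (377), 311 for coating among long nanowires (686), 83 among short (129), 193 for length with PVP (308) and 0 with SiO2 (5). With the array floor as a covariate the counts were 1471 for Ag+, 0 for L-SiO2-NW, 1 for S-PVP-NW, 0 for S-SiO2-NW, 29 for L-PVP-NW against Ag+ (2234), 339 for L-SiO2-NW against Ag+, 1080 for S-PVP-NW against Ag+ (1652), 12 for coating (1463), 0 for length (193), 0 for the interaction (3), 0 and 225 for coating among long and short nanowires, and 0 for length with PVP. There the SE grew 1.12 times for Ag+, 1.92 for L-SiO2-NW, 1.8 for S-PVP-NW, 1.49 for S-SiO2-NW and 1.51 for coating, and log2 differences correlated with those without the covariate at 0.97, 0.63, 0.74, 0.77 and 0.81. All 138, 194 and 679 features kept their sign, as did 1461 of 1463 for coating. A limit on mean intensity over 200, where fewer features are tested, gave 892 for Ag+, 72 for L-SiO2-NW, 194 for S-SiO2-NW, 615, 530, 775 and 223 for L-PVP-NW, L-SiO2-NW, S-PVP-NW and S-SiO2-NW against Ag+, 503 for coating, 213 among long nanowires, 202 for length with PVP and 15 with SiO2.

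Median centring gave 2 for L-PVP-NW, 373 for L-SiO2-NW, 435 for S-PVP-NW, 1860 for S-SiO2-NW, 461 for length, 1189 for coating among long nanowires and 689 for length with PVP; features without overlap with Control numbered 1924 in L-SiO2-NW (1274), 1970 in S-PVP-NW (1254) and 2476 in S-SiO2-NW (1540). The common 75th percentile of raw values gave 7626 for S-SiO2-NW, 6622 for coating, 5733 among long nanowires, 17 for length with SiO2 and 7456 for any difference (3203), with 214 features without overlap in L-PVP-NW (488) and 2876 in S-SiO2-NW. Over bright features it gave 70 for L-SiO2-NW and 2 for the interaction. Array weights gave 24 for L-PVP-NW, 410 for L-SiO2-NW, 359 for S-SiO2-NW, 292 for length, 14 for the interaction, 1608 and 259 for coating among long and short nanowires, and 713 and 16 for length with PVP and SiO2. Trend and robust eBayes gave 7 for L-PVP-NW, 65 for L-SiO2-NW, 107 for length, 84 for coating among short nanowires, and 181 and 11 for length with PVP and SiO2. The residual component as a covariate gave 274 for L-SiO2-NW, 303 for S-PVP-NW, 578 for S-SiO2-NW against Ag+, 5 for the interaction, and 1041 and 234 for coating among long and short nanowires.

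With the replicate number as a replicate block over the 20 numbered arrays, the counts were 2232 for Ag+, 114 for L-SiO2-NW, 194 for S-PVP-NW, 481 for S-SiO2-NW, 826, 1394 and 284 for L-SiO2-NW, S-PVP-NW and S-SiO2-NW against Ag+, 85 for coating among short nanowires and 4 for length with SiO2; 11 gene list results of the 4 exposures with numbers passed (9 without the block). Of 103 named values past the test in these groups, 15 were lost and 5 others passed. Residuals of same-numbered arrays correlated between −0.45 and 0.43, with medians of −0.05, −0.23, −0.06 and −0.05 for numbers 1 to 4, and 6 of 20 arrays correlated best with their own number, so same-numbered arrays do not pair with 1 sign across groups. The split of numbers 1 and 3 from 2 and 4 on the first residual component is reversed in L-SiO2-NW and S-PVP-NW, which a block by number cannot take up; as a covariate the component left 303 for S-PVP-NW and 274 for L-SiO2-NW. No paired analysis was possible for L-PVP-NW because its replicates carry letters.

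Without single arrays the counts ran from 1734 to 2811 for Ag+, 2 to 123 for L-PVP-NW, 18 to 427 for L-SiO2-NW, 104 to 309 for S-PVP-NW and 182 to 1120 for S-SiO2-NW. Against Ag+ they ran from 1172 to 2703 for L-PVP-NW, 580 to 1344 for L-SiO2-NW, 797 to 2211 for S-PVP-NW and 148 to 699 for S-SiO2-NW. They ran from 873 to 1601 for coating, 42 to 274 for length, 0 to 33 for the interaction, 204 to 840 and 3 to 113 for coating among long and short nanowires, 67 to 480 and 0 to 24 for length with PVP and SiO2, 2360 to 3414 for any difference, and 8 to 12 for gene lists.

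Of 50 gene list tests 11 passed; 0 did with an estimated correlation, 24 with fry, 6 with 1 feature per gene name, 7 with the 75th percentile of raw values and 30 against a background of all features. With Control arrays split 2 and 2, correlations between exposures went from 0.41 to 0.14 for Ag+ with L-PVP-NW, 0.48 to 0.23 with L-SiO2-NW, 0.45 to 0.22 with S-PVP-NW and 0.69 to 0.43 with S-SiO2-NW. For L-PVP-NW they went from 0.32 to −0.03 with L-SiO2-NW, 0.44 to 0.09 with S-PVP-NW and 0.28 to −0.03 with S-SiO2-NW, where Control arrays are no longer shared and each difference rests on 2 of them; the cause was not tested. The others went from 0.41 to 0.11 for L-SiO2-NW with S-PVP-NW, 0.70 to 0.34 for L-SiO2-NW with S-SiO2-NW and 0.56 to 0.25 for S-PVP-NW with S-SiO2-NW.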

Other observations

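Single members of lists with fewer than 5 features, which were not tested as lists, also changed in Ag+. These members, like the unnamed features and single spots below, were chosen after values were seen. Heat shock protein 90 fell at both features (DM02180P3, −1.39 ± 0.22, limma adjusted p = 0.000364; DM01059P3, −1.96 ± 0.60, 0.028), as did heat shock protein 60 (DM02811P1, −1.84 ± 0.32, 0.00085). Cytochrome P450 CYP4AB2 (DM02419P1) rose by 1.81 ± 0.41 (adjusted p = 0.005), a thioester-containing immune protein (DM01176P3) by 1.31 ± 0.30 (0.00542) and the replication factor MCM7 (DM00884P2) by 0.42 ± 0.13 (0.0357). In S-SiO2-NW the heat shock protein 90 features had −0.73 (adjusted p = 0.0559) and −2.05 (0.0534). Glutathione transferase (DM01138P4) had −1.01 in L-SiO2-NW (adjusted p = 0.192) and passed in no exposure against Control, and the same holds for 3 chitinase features, 3 protease inhibitors, a chaperonin (DM01385P3), arrestin 1 (DM03055P2) and a phage lysozyme (DM02265P4), the only member of the bacterial list.

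Lists that did not pass camera in Ag+ were vitellogenin (median −1.85, camera adjusted p = 0.0835), oxidative stress (−1.54, 0.266), cuticle (−0.54, 0.443) and hemoglobin (−0.84, 0.443, with 3 of 5 features falling). Nor did ion transport (−0.70, 0.385), mitochondrial respiration (−0.28, 0.882), proteasome and ubiquitin (0.10, 0.586) or digestive enzymes (−0.14, 0.46), whose mean of 0.10 differs in sign from the median. With fry, which tests a list by itself, adjusted p in Ag+ was 0.00175 for vitellogenin, 0.005 for oxidative stress, 0.0085 for hemoglobin, 0.0233 for cuticle and 0.000397 for ion transport, each down. List members carry names because the authors listed them as changed on these arrays, so small fry p-values are in part built in. The oxidative stress result is not separate from yolk, since 8 of its 11 members are vitellogenin features. Outside Ag+ fry also passed, each down, for lists that did not pass camera: ion transport in L-PVP-NW (adjusted p = 0.0348), L-SiO2-NW (0.0131), S-PVP-NW (0.000397) and S-SiO2-NW (0.000397), oxidative stress (0.00721) and hemoglobin (0.0155) in S-PVP-NW, and cuticle (0.039) and mitochondrial respiration (0.0188) in S-SiO2-NW. In L-PVP-NW all lists apart from vitellogenin and oxidative stress had camera adjusted p of 0.219 or more, and camera pointed up where fry pointed down and the median lay below 0, for cuticle (−0.13), digestive enzymes (−0.21) and the proteasome list (−0.08, mean 0.22). The same holds for oxidative stress in S-SiO2-NW (−0.24, adjusted p = 0.882), and in S-PVP-NW mitochondrial respiration had a median of 0.07 and a mean of −0.05. Polyubiquitin (DM01627P1) had 53 on Control 3 and 8807 to 10908 on the other Control arrays, and the proteasome score of Control 3 was −1.931, which raises the mean of this list in every exposure. In L-SiO2-NW the proteasome list had 0.91 (0.148) and vitellogenin 0.44 (0.356); in S-PVP-NW hemoglobin had −0.72 (0.263) and ion transport −0.69 (0.115); in S-SiO2-NW cuticle had −0.60 (0.266), the proteasome list 0.92 (0.149), mitochondrial respiration −1.10 (0.69) and ion transport −0.56 (0.154). Median centring turned the S-SiO2-NW vitellogenin median from −0.25 to 0.36, hemoglobin from −0.23 to 0.21 and oxidative stress from −0.24 to 0.19, and the Ag+ digestive median from −0.14 to 0.03.

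In L-PVP-NW replicates A to D, DM04057P3 had intensities of 18551, 16081, 6664 and 625 and DM11644P3 had 25251, 6734, 4196 and 310, where the other 20 arrays had 53 to 144 and 52 to 107. Single spots more than 32-fold above all other arrays numbered 9, with 3 on Control 3 and 3 on L-PVP-NW A, and 8 lay more than 32-fold below, with 4 on Control 3, such as 40S ribosomal protein S24 (DM02768P1, 54). Of the 154 features that follow the first residual component at r above 0.9 in size, 0 are in the authors' table.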
